A study of Drosophila melanogaster with 13 samples.

How the data were processed

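RNA of dissected Drosophila melanogaster proboscises, with the tissue given as labellum per the labels, had been sequenced in 13 libraries of 4 groups. The sugar diet (n = 2) and control diet (n = 2) libraries held 200 proboscises each and were made with an Ovation kit for model organisms. The OGT RNAi (n = 5) and Gal4 control (n = 4) libraries held 20 proboscises each and were made with the Ovation SoLo kit. Because kit and input differed, each pair of groups was fitted on its own.

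Per the labels, the authors trimmed reads with Trimmomatic 0.22, quantified transcripts with kallisto 0.43 and tested differences with sleuth, for which no version was given. The deposited tables hold, for each library, the estimated counts per transcript (expected counts) that the authors made with kallisto without normalization, 54.7% of them not whole numbers. They also hold the authors' TPM, that is transcript abundance scaled within the library by kallisto, and the effective transcript length in bases. The deposited result tables give the authors' effect b and its standard error on a natural-log (ln) scale, with p-values and q-values. The genome build, the annotation release, and the model and filters of the authors were not stated. The authors' tables list 30449 targets, of which 30447 are transcripts and the others are Gal4 and EGFP sequences. Gene positions were taken from the BDGP6 annotation, release 6 of the genome. Of 9937 genes with a position in the authors' tables as well, 9888 had the identical position and 9932 lay within 5000 bases.

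Estimated counts were summed per gene (13894 genes) and rounded. A set of 50 transcripts without a gene, holding 0.042 to 0.057% of counts, was left out. Total counts per library ranged from 5632598 to 13885005. At these depths a count of 0 allows up to 3 counts, that is 0.216 to 0.533 CPM (counts scaled to the library total), for counting error only, as reads had no molecular identifiers. Across all libraries 179 genes with more than 50 counts had the same counts as another gene. Their values are not separate measurements.

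Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by the trimmed mean of M-values (TMM) and tested with the robust quasi-likelihood F test of edgeR 4.0.16, two-sided, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method within each of the 2 comparisons, and a gene was called at an adjusted p under 0.05. Given levels are TMM-normalized CPM as mean ± SD, and log2 changes are those of the edgeR fit. A gene counted as separated when no value of one group lay within the range of the other. Gene lists with 3 or more tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at its preset correlation of 0.01, and adjusted over the lists of the comparison. Camera with an estimated correlation and fry were run beside it. For each list the members were also adjusted over the list alone. Shared calls were tested with a two-sided Fisher's exact test over the genes tested in both comparisons. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

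The groups, tests, lists, alternative settings and the rule for naming genes were fixed before the data were examined. The rule named sxc and each measured sweet taste receptor. Among called, separated genes with a mean of 5 CPM or more it named the 10 with the largest positive and the 10 with the largest negative log2 change. It named up to 4 called members of each list with the smallest adjusted p, or where none was called up to 2 with the smallest p. It also named the 6 genes called in both comparisons with the smallest p in both together. Of the genes the rule picked, 1 is not reported here. The 36 lists covered receptors (sweet, bitter, and ionotropic receptors with ppk channels), synaptic vesicle release, neuronal excitability, G protein and phospholipase C signalling, the hexosamine pathway, glycolysis, the TCA cycle, oxidative phosphorylation, ribosomal proteins, and maltases and amylases. They covered lipogenesis, lipid breakdown, insulin, FOXO and AKH signalling, heat shock proteins and the unfolded protein response of the endoplasmic reticulum (ER). Others were glutathione transferases and cytochrome P450s, antimicrobial peptides, odorant-binding proteins, cuticle proteins, the circadian clock, Polycomb and Hox genes, and marker genes of transgenes. Cell type lists were neurons, glia, muscle, fat body, haemocytes, eye photoreceptors, maxillary palp olfactory neurons, support cells of taste sensilla, gut, tracheal and epidermal cells, and male and female tissue.

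The test was tested on simulated data with changes of 1.5, 2 and 4-fold. At the size of the diet comparison it found 37.3, 76.1 and 95.5% of changed genes, with 7 false calls among the unchanged of 8676 tested genes. At the size of the RNAi comparison it found 76.1, 97 and 100%, with 8 false calls among the unchanged of 9334. Each gene was simulated independently with the spread typical of its level. Correlated genes and libraries of differing tissue content were not simulated, so these rates are a best case. Replicates were checked for duplicated libraries, and none of the pairs differed by as little as counting error gives. Alternatives fixed beforehand were RLE size factors, no filter, a block for the replicate number, leaving out each library and a transcript length offset. Further ones were DESeq2 1.42.0, limma on log2(TPM + 0.5), a single fit of all 4 groups, camera with an estimated correlation, fry, a minimum change of 1.5-fold and, for shared calls, unadjusted p-values. Alternatives added after seeing the data left out Gal4 control replicates 3 and 4, left out OGT RNAi replicates 1 and 2, or removed a transcript length trend from each library (lowess span 0.3). Others removed the counts of Arc1 and CG15579, or kept 1 gene of each set with identical counts. The transcript-level results of the authors were read for their units and not compared, as all tests here are per gene.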

Results

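Transcript levels were measured by RNA sequencing in the proboscis of Drosophila melanogaster, the mouthpart whose tip, the labellum, carries taste hairs. In the first experiment, flies of the parental genotype were kept for 7 days on a high sugar diet (n = 2) or on a control diet (n = 2). In the second experiment all flies spent 7 days on the sugar diet and carried Gr5a-GAL4, a driver active in sweet taste neurons. They carried it with a UAS transgene for RNA interference against OGT (n = 5) or without that transgene (Gal4 control, n = 4). OGT is the O-GlcNAc transferase, encoded by sxc (FBgn0261403), which adds a sugar made by the hexosamine pathway to proteins. Total counts were 5632598 and 6481195 in the sugar diet libraries and 7559788 and 8105908 in the control diet libraries. They were 13885005, 11694752, 12556453, 8183523 and 13133861 in OGT RNAi replicates 1 to 5. In Gal4 control replicates 1 to 4 they were 13467517, 11655131, 11067647 and 11776537. The series text calls the replicates biological without saying how the pools of flies were formed, so the p-values measure the spread between these samples.

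The first comparison asked which transcripts of the proboscis differ after 7 days on the sugar diet. Some transcripts for starch digestion, fatty acid synthesis, glycolysis and antimicrobial peptides were lower on the sugar diet, and some for cuticle proteins and muscle proteins were higher. Their lists were called at the preset correlation of the list test, and with an estimated correlation 0 lists of this comparison were called. Among called, separated genes of 5 CPM or more the largest drop was that of Amy-p, an alpha-amylase that digests starch (FBgn0000079, 2R from 17118636 to 17120303). It had 17.0 ± 0.214 CPM on the sugar diet and 95.6 ± 6.77 CPM on the control diet (n = 2 each), a log2 change of -2.49 (SE 0.123, adjusted p = 4.45e-09). FASN1, a fatty acid synthase (FBgn0283427, 2L from 3056598 to 3068177), had 428 ± 15.2 and 1010 ± 12.1 CPM (log2 change -1.24, adjusted p = 4.9e-08). Neither sxc nor any tested sweet taste receptor was called. Of 8825 tested genes, 571 were called, 275 higher and 296 lower, and 312 of them changed by at least 1.5-fold (127 higher and 185 lower). All 571 were separated. Of the tested genes 47.5% were, and chance separates 33.3% in groups of this size.

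**Figure D1:**
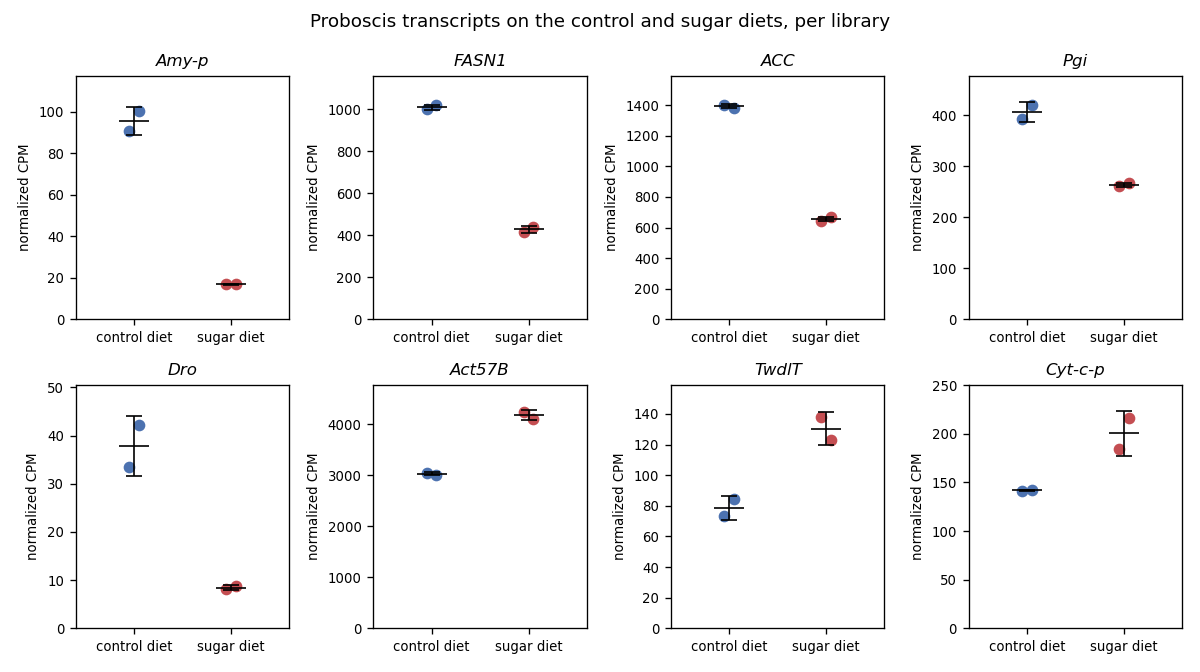
Normalized CPM (y axis, from 0) of 8 genes in the sugar diet and control diet libraries, with 1 point per library (n = 2 per group) and the mean with its SD. Amy-p, FASN1, ACC, Pgi and Dro were lower on the sugar diet (Amy-p 17.0 against 95.6 CPM), and Act57B, TwdlT and Cyt-c-p were higher (Act57B 4172 against 3029 CPM).

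Some genes for enzymes that break down starch or make fat were lower on the sugar diet. In the list of maltases and amylases, 3 of 8 tested members fell (3 adjusted over the list alone), Amy-p, its neighbour Amy-d (log2 change -1.87) and Mal-B2 (-0.58). The list was lower with a median of -0.41 and an adjusted p of 0.000709, or 0.0575 without the filter on low counts. Of 20 lipogenesis genes, 10 fell and 1 rose (11 and 2 adjusted over the list alone), with a list median of -0.33 and an adjusted p of 0.000233. The falling ones included ACC, the acetyl-CoA carboxylase that commits carbon to fatty acids (FBgn0033246, 2R from 7974115 to 7991862). ACC had 655 ± 15.2 CPM on the sugar diet and 1395 ± 13.4 CPM on the control diet (n = 2 each, log2 change -1.09). AcCoAS, an acetyl-CoA synthetase, fell by 0.97 and Desat1, a fatty acid desaturase, fell by 0.88 on the log2 scale. The member that rose was sug (sugarbabe), a sugar-responsive transcription factor (log2 change 1.63). In the glycolysis list 3 of 13 members fell (4 adjusted over the list alone), Pgi, PyK and Hex-C, with log2 changes of -0.62, -0.45 and -0.79. All 13 members had negative log2 changes (median -0.17, adjusted p = 0.000758). Of 17 lipid breakdown genes 4 fell (7 adjusted over the list alone), among them the triglyceride lipase bmm (-0.55), whd (-0.41), yip2 (-0.42) and CG3902 (-0.38), with a median of -0.22 and an adjusted p of 0.00108. The calls of these lists were lost with an estimated correlation, where each had an adjusted p = 0.551. Leaving out control diet replicate 1 or 2 lowered the calls of the comparison to 195 and 228. In at least 1 of these cases the calls of PyK, Hex-C, CG3902, whd, yip2, Mal-B2 and sug ended.

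Some antimicrobial, detoxification and fat body genes were also lower. Of 24 antimicrobial and immune effector genes 5 fell and none rose (8 adjusted over the list alone), with a median of -0.50 and an adjusted p of 0.000709. Dro, the antimicrobial peptide drosocin, had 8.45 ± 0.486 CPM on the sugar diet and 37.9 ± 6.2 CPM on the control diet (n = 2 each, log2 change -2.16). Def (defensin), Drs (drosomycin) and PGRP-SC2 fell by 1.92, 2.10 and 2.06 on the log2 scale, the last 2 from levels of 4.98 and 3.35 CPM. The calls of Drs, PGRP-SC2 and, among the genes below, GstZ2, apolpp and Est-6 ended without control diet replicate 1 (195 genes called), and those of PGRP-SC2, GstZ2, apolpp and Mtp without replicate 2 (228). Of 77 glutathione transferases and cytochrome P450s 5 fell and 1 rose (7 adjusted over the list alone), with a median of -0.16 and an adjusted p of 0.0334. The P450 genes Cyp6g1 and Cyp28d1 fell by 0.99 and 1.18 and GstZ2 fell by 0.43. In contrast Cyp4g1, a P450 of cuticular hydrocarbon synthesis, rose from 0.597 to 8.32 CPM (log2 change 3.76). Of the 6 fat body markers 4 fell and 1 rose (5 adjusted over the list alone), with a median of -0.61 and an adjusted p of 0.0334. Lsp1beta, a storage protein, fell by 1.35, Est-6 fell by 1.09, Mtp fell by 0.82 and apolpp, the precursor of the lipid carrier lipophorin, fell by 0.40 on the log2 scale. The gene to (takeout) rose by 1.01. With an estimated correlation these 3 lists had an adjusted p = 0.551. Without control diet replicate 2 the median of the antimicrobial list was -0.21, and without the filter that of the fat body list was -0.97. Leaving out sugar diet replicate 1 ended the call of the antimicrobial list (median -0.22, adjusted p = 0.365) and of the P450 list (median -0.10, adjusted p = 0.296). The P450 list also lost its call without control diet replicate 1 (median -0.08, adjusted p = 0.248) or without the filter (0.0607), and the fat body list without sugar diet replicate 2 (0.177) or control diet replicate 2 (0.078).

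Some cuticle, muscle and respiratory genes were higher on the sugar diet. Of 33 cuticle protein genes 9 rose and none fell (11 and 1 adjusted over the list alone), with a median of 0.66 and an adjusted p of 6.33e-07. The median was 0.35 without sugar diet replicate 1 and 0.44 without the filter on low counts. TwdlT had 130 ± 10.6 and 78.7 ± 7.99 CPM (log2 change 0.72). Cpr49Ah, Cpr49Ae and TwdlE rose by 1.16, 0.83 and 0.92. Of 16 muscle genes 8 rose (15 adjusted over the list alone), with a median of 0.35 (0.21 without sugar diet replicate 1) and an adjusted p of 5.22e-06. The actin gene Act57B had 4172 ± 99.0 and 3029 ± 30.0 CPM (log2 change 0.46). The tropomyosin gene Tm1 rose by 0.47, the myosin light chain gene Mlc2 by 0.37 and the giant muscle protein gene bt by 0.42. Of 64 genes of oxidative phosphorylation 10 rose (16 adjusted over the list alone), with a median of 0.22 and an adjusted p of 5.22e-06. Genes of the mitochondrial genome took 7.38 to 9.07% of counts in the sugar diet libraries and 10.4 to 10.71% in the control diet libraries. These shares are not TMM-normalized. Arc1 alone took 12.63 and 13.4% of counts in the sugar diet libraries and 7.4 and 7.51% in the control diet libraries. The mitochondrial shares therefore cannot be set beside the log2 changes of the list. Among the genes that rose were Cyt-c-p (cytochrome c, 0.50), UQCR-11 (0.57), COX5B (0.54) and ATPsynF (0.43). With an estimated correlation the muscle list had an adjusted p = 0.608 and the other two an adjusted p = 0.551. On the TPM scale, where the median of all genes was shifted to -0.27, the oxidative phosphorylation list had a median of -0.08, which relative to that shift is 0.19. The muscle and cuticle lists had medians of 0.07 and 0.38 there, relative to the shift 0.34 and 0.64, and limma on that scale called 0 of the muscle and 0 of the oxidative phosphorylation genes. The calls of Act57B, Mlc2, bt, Cyt-c-p and ATPsynF ended without control diet replicate 1 and without replicate 2, when 195 and 228 genes were called, and those of Tm1, UQCR-11, COX5B, Cpr49Ae and TwdlE in at least 1 of these cases.

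Taste receptors and neuronal genes showed few calls. The sweet taste receptors had low levels, with Gr64e at 5.76 ± 0.237 and 7.32 ± 1.5 CPM (n = 2 each, log2 change -0.34) and Gr5a at 1.79 and 2.07 CPM (-0.17). Gr64b and Gr64c share 1 annotated span (3L from 4028605 to 4032032) and had the same counts, 7.20 and 9.18 CPM (-0.34). Gr64d had a log2 change of -0.07, which turned positive without sugar diet replicate 2 (0.02) and with a length offset (0.06). That of Gr5a turned positive without sugar diet replicate 1 (0.205) or control diet replicate 2 (0.064). None of the 5 tested sweet receptors and none of 6 bitter receptors was called by edgeR, DESeq2 or limma, and 0 of each had an unadjusted p under 0.05 or passed adjusted over the list alone. The sweet list had a median of -0.34 (adjusted p = 0.0965) and the bitter list, with Gr8a at -0.95 and Gr66a at -0.55, a median of -0.27 (adjusted p = 0.154). Of 10 ionotropic receptors and ppk channels 1 rose, Ir47a (1.12), and adjusted over the list alone 1 was higher and 4 lower. Ir47a lost its call without sugar diet replicate 2 (938 genes called in all) or either control diet replicate (195 and 228). The target of the second experiment, sxc, had 50.2 ± 3.38 and 55.1 ± 1.84 CPM (log2 change -0.14, adjusted p = 0.596), and its settings ranged from -0.40 to -0.07 without a call. In the hexosamine list, with CG1969 at -0.54 and mmy at 0.25 (-0.04 on the TPM scale), edgeR and DESeq2 called 0 of 7 genes, 0 had an unadjusted p under 0.05, and limma on TPM called 1. Its list test pointed down (adjusted p = 0.789) and its median was 0.01.

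Among ion channels, 4 potassium channel genes rose, SK (0.38), Shab (0.35), slo (0.34) and Sh (0.31, but -0.04 on the TPM scale), while the sodium channel gene NaCP60E, outside the naming rule and chosen after its values were seen, fell by 0.29. That excitability list of 19 genes was not called (5 adjusted over the list alone, adjusted p = 0.95), and the 4 potassium channel calls ended without control diet replicate 1 or 2 (195 and 228 genes called). In synaptic vesicle release 1 of 23 genes fell, cpx (complexin, -0.47; 1 adjusted over the list alone, adjusted p = 0.442). In G protein signalling 1 of 19 rose, rdgA, a diacylglycerol kinase gene (0.77; 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.503). Both lost their call without control diet replicate 2. Members of the clock list went in both directions: 4 of 10 rose and 2 fell (7 adjusted over the list alone, adjusted p = 0.442), with vri at 0.35, tim at 0.44 and cry at -0.62. The other fall, Nmdmc (-1.60), is an enzyme of folate metabolism that the list as fixed beforehand held, and it is no clock gene. Odorant-binding protein genes fell in 3 of 20 cases, Obp99c (-0.84), Obp99b (-1.89) and Obp49a (-0.33), with 5 adjusted over the list alone and an adjusted p of 0.109. In the TCA cycle 3 of 19 genes fell, skap (-0.40), Mdh1 (-0.38) and Idh (-0.27; 3 higher and 3 lower adjusted over the list alone, adjusted p = 0.684). Of 82 ribosomal protein genes RpL10Ab (-0.42) and RpS26 (-0.34) fell and RpS3 (0.33) rose (3 adjusted over the list alone, adjusted p = 0.313). Heat shock genes rose in 2 of 17 cases, Hsp23 (1.92) and Hsp83 (0.33; 4 adjusted over the list alone, adjusted p = 0.171). In the ER list of 19, Sec61alpha (-0.39) and the chaperone Hsc70-3 (-0.29) fell (3 adjusted over the list alone, adjusted p = 0.0771). In insulin, FOXO and AKH signalling 1 of 20 fell, the gluconeogenic Pepck (-0.38; 1 adjusted over the list alone, adjusted p = 0.789), whose counts were identical to those of CG45087. Without control diet replicate 1 or 2 the calls of vri, tim, skap, Mdh1, Idh, RpL10Ab, RpS26, RpS3, Hsp83, Sec61alpha, Hsc70-3, Obp49a and Pepck ended, as did that of Obp99b without replicate 2. Those of Sh, Obp49a, Sec61alpha and Hsc70-3 also ended without sugar diet replicate 1 (819 genes called).

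Markers of other cell types moved in part. In glia 2 of 10 rose, nrv2 (0.61) and repo (0.58; 3 higher and 2 lower adjusted over the list alone, adjusted p = 0.442). In haemocytes 1 of 9 rose, the collagen gene vkg (0.64; 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.442). Of 8 support cell genes 1 fell, Obp49a (3 adjusted over the list alone, adjusted p = 0.313). Neuron markers (11 genes) included fne at 0.34 and elav at 0.18, which was -0.16 on the TPM scale (list adjusted p = 0.499). Eye photoreceptor markers (3 genes) included rdgB at -0.06 and norpA at -0.09, which was 0.06 without control diet replicate 1 (list adjusted p = 0.789). Tracheal and epidermal markers (11 genes) included t and yellow-c at -0.35 each (list adjusted p = 0.963). Polycomb genes (18) included ph-d at -0.19 and Jarid2 at -0.16 (list adjusted p = 0.95), and Hox genes (6) included pb at -0.19 and Scr at -0.18 (list adjusted p = 0.47). None of these genes was called, and 1 tracheal gene passed adjusted over the list alone. The 10 lists without an edgeR call, the short palp and sex lists included, held 70 tested members, of which 8 had an unadjusted p under 0.05. DESeq2 called 0 of them and limma on TPM 2. The Polycomb test pointed down with a median of 0.02. In lists too short to test, v (vermilion, -1.37) and the gut protease gene Jon25Bi (-0.90) fell. Orco (-1.73), Or71a (0.20, negative without sugar diet replicate 1 at -0.28 or control diet replicate 1 at -0.17) and msl-2 (-0.23) were not called. The calls of vkg and v ended without control diet replicate 1 (195 genes called) and, with those of nrv2 and repo, without replicate 2 (228).

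The remaining genes named by size of change were mixed in function. CG3999, a glycine decarboxylase, fell from 36.5 ± 6.63 to 7.09 ± 0.311 CPM (n = 2 each, log2 change -2.36), and CG11089, an enzyme of purine synthesis, from 139 ± 6.69 to 41.6 ± 8.34 CPM (-1.75). CG16836, CG34166, CG13704 and CG33307 fell by 2.03, 1.88, 1.79 and 1.70 on the log2 scale. Besides Hsp23 and sug, the largest rises among separated genes of 5 CPM or more were those of CG6280 (1.80), CG15080 (1.62), CG9777 (1.39), CG9411 (1.34), Cpr62Bc (1.32), CG43333 (1.32), Pen (1.26) and CG13643 (1.25). The calls of sug, Cpr62Bc and Pen ended without control diet replicate 1 (195 genes called), and those of CG15080, Cpr62Bc and CG13704 without replicate 2 (228). The single most abundant gene, Arc1, chosen after its values were seen, had 139700 ± 1286 and 69590 ± 581 CPM (log2 change 1.01).

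The size of the gene set moved with the method and with single libraries. DESeq2 called 306 genes and a single fit of all 4 groups 300, and the calls were 938 without sugar diet replicate 2, 195 without control diet replicate 1 and 228 without control diet replicate 2. Limma on the TPM scale called 505, of which 59 were higher and 446 lower (11.7% higher against 48.2%). That scale has no TMM correction and the median log2 change of all genes was -0.27 on it, which favours lower calls. Of the 88 called genes picked by the naming rule, 33 stayed called whichever single library was left out, including Amy-p, Amy-d, FASN1, ACC, AcCoAS, Desat1, Pgi, bmm, Dro, Def, Cyp6g1, Cyp4g1, Lsp1beta, TwdlT, Cpr49Ah, cry and Nmdmc. None of the 88 changed direction when 1 library was left out. The authors' table has 454 genes with a q-value under 0.05, of which 433 were called here as well, all in the same direction.

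The second comparison asked what RNA interference against OGT in sweet taste neurons changed in the proboscis of flies on the sugar diet. A cuticle protein gene, a G protein subunit gene and several detoxification genes were higher with OGT RNAi, and fru and CG33110 were lower. The Gal4 control lacked the UAS transgene. Effects of RNA interference therefore cannot be told apart from those of the transgene or of the strain that carried it. Lcp65Ag2, a larval cuticle protein gene (3L from 6132990 to 6133593), had 73.7 ± 12.8 CPM (n = 5) with OGT RNAi and 28.8 ± 4.61 CPM (n = 4) in the Gal4 control. Its log2 change was 1.36 (adjusted p = 0.00123). The gene fru, a transcription factor of sex-specific neurons, had 129 ± 6.74 CPM (n = 5) and 179 ± 22.4 CPM (n = 4), a log2 change of -0.47 with an adjusted p of 0.0104. The target sxc was not called. Ribosomal protein genes as a list were higher and sweet receptor genes as a list lower, 2 calls of the list test that ended with an estimated correlation (adjusted p = 0.967 each). Of 9400 tested genes 119 were called, 98 higher and 21 lower, and 65 of them changed by at least 1.5-fold (56 higher and 9 lower). Of the 119, 110 were separated. Of the tested genes 5.5% were, and chance separates 1.59%.

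**Figure D2:**
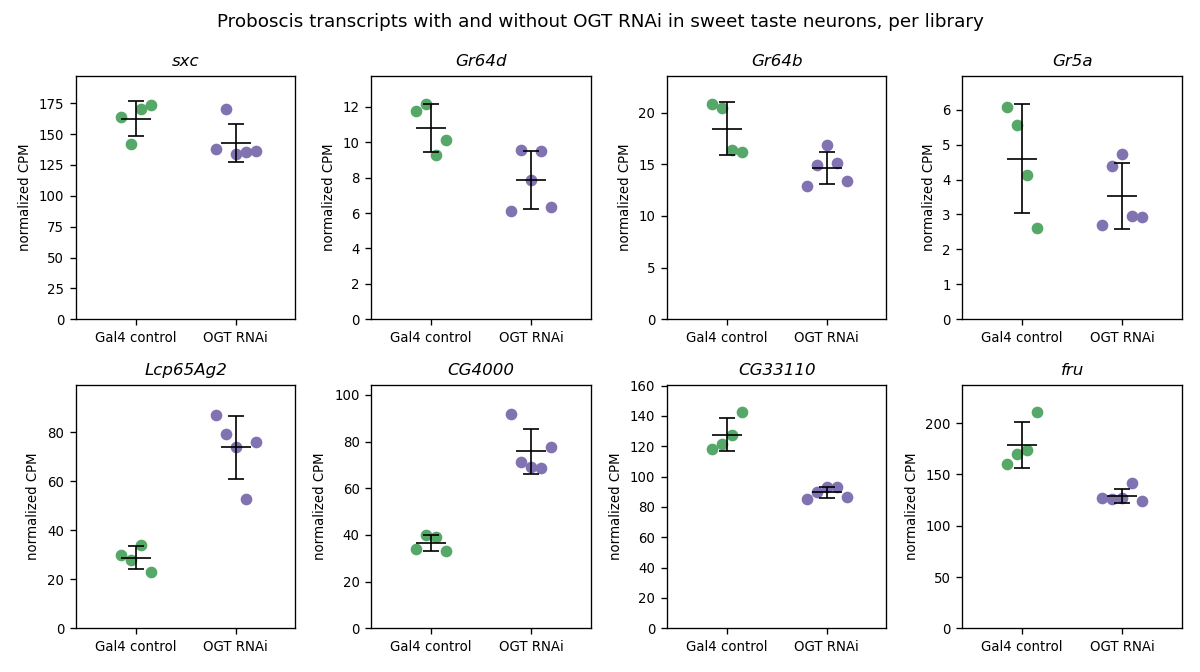
Normalized CPM (y axis, from 0) of 8 genes in the OGT RNAi (n = 5) and Gal4 control (n = 4) libraries, with 1 point per library and the mean with its SD. Lcp65Ag2 and CG4000 were higher with OGT RNAi (CG4000 75.8 against 36.6 CPM) and CG33110 and fru lower, while sxc (142 against 162 CPM), Gr64d, Gr64b and Gr5a were not called.

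The RNAi target sxc (2R from 5307288 to 5329555) had 142 ± 15.5 CPM (n = 5) with OGT RNAi and 162 ± 14.3 CPM (n = 4) in the control. The log2 change was -0.19 (SE 0.0859) with an adjusted p of 0.376. It lay between -0.27 and -0.10 over all settings and was never called. The driver is active in a subset of taste neurons, whereas each library held RNA of whole proboscises. The Gal4 transcript itself had 11 to 18 counts with OGT RNAi and 20 to 41 counts in the control, 1.35 and 2.38 CPM (log2 change -0.86, adjusted p = 0.143). It had 0 counts in each diet library, which allows up to 0.37 to 0.533 CPM. EGFP had 0 counts in each library.

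Of 8 sweet taste receptor genes 0 were called by edgeR, DESeq2 or limma, 3 had an unadjusted p under 0.05, and 2, Gr64d and Gr64b, passed when adjusted over the list alone. As a list they were lower, with a median of -0.34 and an adjusted p of 0.0494, and an adjusted p = 0.967 with an estimated correlation. Gr64d had 7.87 ± 1.65 CPM (n = 5) with OGT RNAi and 10.8 ± 1.36 CPM (n = 4) in the control (log2 change -0.48, adjusted p = 0.158). Gr64b had 14.7 ± 1.55 and 18.4 ± 2.55 CPM (-0.34, adjusted p = 0.175). Gr64c, Gr64e, Gr64f and Gr5a had log2 changes of -0.29, -0.34, -0.38 and -0.39, and Gr61a and Gr64a of 0.34 and 0.12. Gr64b and Gr64c, which share an annotated span, had the same counts in each library except OGT RNAi replicate 4. The 8 genes are therefore not 8 separate measurements, and the setting with 1 gene of each identical set kept both. The log2 change of Gr64a was -0.02 without Gal4 control replicate 4 and -0.09 without replicates 3 and 4. The list lost its call without OGT RNAi replicate 1 (median -0.27, adjusted p = 0.0727) or 5 (-0.28, 0.119) and without Gal4 control replicate 1 (-0.25, 0.139) or 2 (-0.29, 0.116). It was also lost with RLE factors (adjusted p = 0.0622), a length offset (0.0823), the length trend removed (0.0762), OGT RNAi replicates 1 and 2 left out (0.14) and 1 gene of each identical set (0.0584).

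The 82 ribosomal protein genes had positive log2 changes without exception, with a median of 0.12 and an adjusted p of 2.78e-10 for the list. Examples were RpS24 (0.23) and RpL13A (0.20). None of the 82 was called by edgeR, DESeq2 or limma (0 adjusted over the list alone), and 15 had an unadjusted p under 0.05. The 64 oxidative phosphorylation genes were higher with a median of 0.06 (adjusted p = 0.0497), with ND-MLRQ at 0.15 and ND-PDSW at 0.16. Calls by edgeR, DESeq2 and limma were 0, with 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. The 20 genes of insulin, FOXO and AKH signalling were lower with a median of -0.12 (adjusted p = 0.0343), with Ilp6, an insulin-like peptide gene, at -0.42 and REPTOR at -0.28. Again edgeR, DESeq2 and limma called 0, with 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. With an estimated correlation these 3 lists had an adjusted p = 0.967. Across genes, log2 changes fell with transcript length (Spearman -0.255 over 9400 genes, which are not independent replicates), with medians of 0.06 among the shortest and -0.06 among the longest 20% of transcripts. The oxidative phosphorylation list lost its call without OGT RNAi replicates 3, 4 or 5 (adjusted p = 0.137, 0.619 and 0.192) or Gal4 control replicates 1 or 4 (0.227 and 0.272), with medians down to 0.03, and with RLE factors (0.0659) or 1 gene of each identical set (0.066). With the length trend removed its median was -0.005, and that of the ribosomal list was 0.05. The insulin list lost its call without OGT RNAi replicates 4 or 5 (0.0892 and 0.119) or Gal4 control replicates 3 or 4 (0.0616 and 0.191), and with the length trend removed (0.117). Its median was -0.19 without OGT RNAi replicate 2 and -0.20 without Gal4 control replicate 2. Without Gal4 control replicates 3 and 4 both lost it (0.346 and 0.557), and the ribosomal list kept its call (median 0.14, adjusted p = 2.74e-09). Without OGT RNAi replicates 1 and 2 the medians of the ribosomal, oxidative phosphorylation and insulin lists were 0.18, 0.11 and -0.20.

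Of 26 cuticle protein genes 4 rose and none fell (11 and 3 adjusted over the list alone), with a median of 0.27, an adjusted p of 0.00362 and an adjusted p = 0.397 with an estimated correlation. Its median was 0.17 without OGT RNAi replicate 5, and without the filter on low counts it was 0.09 with an adjusted p of 0.725. The 4 genes were Lcp65Ag2, Cpr65Au (3324 ± 268 CPM, n = 5, against 2386 ± 266 CPM, n = 4, log2 change 0.48), Cpr57A (0.37) and Cpr97Eb (0.61). Cpr97Eb was also the 1 called gene of 11 on the list of support cells (2 adjusted over the list alone, adjusted p = 0.0994). Glutathione transferases and cytochrome P450s, enzymes that modify foreign compounds, rose in 5 of 79 cases (12 higher and 5 lower adjusted over the list alone), with GstE5 at 0.69, Cyp6a23 at 0.57, Cyp4p3 at 0.86 and Cyp6a21 at 0.43. The list itself was not called (median 0.02, adjusted p = 0.663). Of 20 lipogenesis genes 1 rose, mdy, a diacylglycerol acyltransferase gene (0.42; 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.39), and of 13 heat shock genes 1, Hsp22 (0.56; 2 adjusted over the list alone, adjusted p = 0.631). Of these genes Lcp65Ag2, GstE5 and Cyp6a23 kept their call whichever library was left out, and the others lost it without Gal4 control replicate 1 or 4 (43 and 42 genes called).

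The strongest call was CG4000 (3R from 20676224 to 20677351). It had 75.8 ± 9.67 CPM (n = 5) with OGT RNAi and 36.6 ± 3.44 CPM (n = 4) in the control, a log2 change of 1.05 with an adjusted p of 0.000202. Galphaf, a G protein alpha subunit gene, rose by 0.94 from 29.6 to 56.6 CPM. CG17716 (2.24), CG10359 (1.75), CG2837 (1.35), CG14291 (1.27), CG16820 (1.11), CG31871 (1.00) and CG8539 (0.93) were the other large rises among separated genes of 5 CPM or more. Adgf-A, a secreted adenosine deaminase gene, fell by 0.62, CG18278 and CG14298 by 0.55 each, CG33110 and CG2321 by 0.51 each, CG5810 by 0.50, CG31705 by 0.44 and Glut4EF by 0.43. The calls of CG17716, CG10359, CG31871, CG8539, Adgf-A, CG18278, CG14298, CG2321, CG5810, CG31705 and Glut4EF ended without Gal4 control replicate 1 (43 genes called).

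The other lists had no edgeR call. ImpL3, the lactate dehydrogenase gene of glycolysis, had 25.9 and 10.1 CPM (log2 change 1.38, adjusted p = 0.052). In lipid breakdown were bmm (-0.49, adjusted p = 0.0612) and CG9527 (0.27), and among clock genes tim (0.37) and to (1.34). Adjusted over the list alone, 1 glycolysis gene, 2 of lipid breakdown, 3 antimicrobial, 2 clock, 1 fat body, 1 haemocyte and 2 eye genes passed. No member of the bitter, ionotropic, synaptic, excitability, G protein, hexosamine, TCA, maltase, ER, odorant-binding, Polycomb, Hox, neuron, glia, muscle or tracheal lists did. The lists nearest to a call were G protein signalling (20 genes, median -0.10, adjusted p = 0.0506), neurons (11, -0.12, 0.0782), synaptic vesicle release (23, -0.09, 0.0946), ionotropic receptors (13, -0.13, 0.0946), glia (10, -0.06, 0.107), excitability (20, -0.06, 0.108) and eye photoreceptors (4, -2.49, 0.108). The OGT RNAi libraries differed among themselves in 2 neuron markers chosen after their values were seen. The sodium channel gene para had 136.8 and 160.6 CPM in replicates 1 and 2 and 37.8 to 50.1 CPM in the others, and fne had 36.8 and 49.1 against 11.96 to 14.9 CPM (68.1 to 121.8 and 15.5 to 35.3 CPM in the Gal4 control). Without these 2 libraries the lists of neurons, synaptic vesicle release, excitability and G protein signalling were called lower at the preset correlation (medians of -0.36, -0.24, -0.26 and -0.22), as was the Polycomb list (-0.10). The 2 libraries were left out because of their high levels of para and fne. Lower neuronal lists without these libraries follow from that choice and are no separate evidence. The ionotropic list was called lower at the preset correlation without Gal4 control replicates 3 and 4 (median -0.25). Without these 2 control libraries the G protein list, which also holds photoreceptor genes such as trpl, had a median of 0.03 (camera adjusted p = 0.579). With all libraries and an estimated correlation, the ionotropic, neuronal, G protein and Polycomb lists each had a camera adjusted p = 0.967. Of the others, the list adjusted p was 0.699 for bitter receptors, 0.563 for the hexosamine pathway, 0.863 for glycolysis, 0.939 for the TCA cycle, 0.739 for maltases and 0.81 for lipid breakdown. It was 0.724 for the ER list, 0.341 for antimicrobial genes, 0.902 for odorant-binding proteins, 0.939 for the clock, 0.606 for Polycomb and 0.863 for Hox genes. In cell type lists it was 0.81 for muscle, 0.724 for the fat body, 0.939 for haemocytes and 0.61 for tracheal and epidermal cells. Over the 31 lists without an edgeR call, which held 507 tested memberships, 68 had an unadjusted p under 0.05, DESeq2 called 15 and limma on TPM 3. Median and test or mean differed in sign in the lists of glycolysis, the TCA cycle, maltases, odorant-binding proteins, the clock, muscle, fat body and haemocytes. Photoreceptor transcripts stood out in Gal4 control replicates 4 and 3, where ninaE, the main rhodopsin gene, had 576 and 27.7 CPM against at most 1.6 CPM elsewhere. The gut protease gene Jon25Bi had 31.1 ± 33.5 CPM (n = 5) and 87.7 ± 17.96 CPM (n = 4, log2 change -1.55).

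Other named members of these lists, some of which passed adjusted over the list alone, were Gr93b (0.61) and Gr59a (0.64) among bitter receptors, Ir94e (-0.57) and ppk (-0.16), VAChT (-0.21) and unc-13 (-0.29), Shal (-0.15) and Ca-alpha1D (-0.14), trpl (-4.78) and Galphai (-0.18), and Gfat1, the first enzyme of the hexosamine pathway (0.19). In metabolism they were Pgk (0.10), SdhD (0.15), skap (-0.14), Mal-B1 (1.05) and Mal-A1 (-0.20). Others were Ero1L (0.45), Herp (-0.20), CG43202 (-0.71), Drsl4 (0.33), Obp57c (0.24), Obp56e (-0.55), Asx (-0.13), Jarid2 (-0.08), Antp (-0.19) and Scr (0.12, or -0.02 without OGT RNAi replicates 1 and 2). Cell type markers were CadN (-0.28), loco (-0.20), alrm (-0.31), TpnC73F (0.22), Act88F (0.54), Lsp1beta (0.55), the prophenoloxidase genes PPO1 (1.54) and PPO2 (1.18), ninaE (-7.48), e (0.54) and Cad74A (0.32). In lists too short to test were w (-0.13), v (-0.02), Or71a (-0.29), Orco (-0.14, or 0.42 without Gal4 control replicate 2) and msl-2 (-0.03, or 0.01 without Gal4 control replicate 1). The gene v was positive without OGT RNAi replicate 1 (0.11) and without Gal4 control replicate 3 (0.06) or 4 (0.12).

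The number of calls depended on single libraries. It was 4 without the photoreceptor-rich Gal4 control replicates 3 and 4. It was 71 without OGT RNAi replicates 1 and 2, which had more para and fne. It was 68, 64 and 265 without OGT RNAi replicate 1, 3 or 4, and 43, 73, 70 and 42 without Gal4 control replicate 1, 2, 3 or 4. DESeq2 called 254 genes (162 higher and 92 lower, 63.8% higher against 82.4%), limma on TPM 87 (60 and 27, 69% higher), the single fit of 4 groups 165 (116 and 49, 70.3% higher), and 53.6% were higher without OGT RNAi replicate 4. Lcp65Ag2, CG4000, Galphaf and CG5773 were called under each setting run. Of the 33 called genes picked by the naming rule, 13 stayed called whichever single library was left out, including these 4, CG2837, CG14291, CG16820, CG33110, fru, GstE5, Cyp6a23 and MtnA. The authors' table has 275 genes with a q-value under 0.05, of which 112 were called here, all in the same direction. It gives sxc an effect of -0.128 on the natural-log scale with a q-value of 0.203.

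The third comparison asked whether genes that differ with diet also differ with OGT RNAi on the sugar diet. Of 8614 genes tested in both, 550 were called by diet and 103 by RNAi, and 13 were shared against 6.58 expected by chance (two-sided Fisher's exact test, p = 0.0224, 0.0559 adjusted over 5 tests). Genes higher on the sugar diet and lower with OGT RNAi numbered 5 against 0.629 expected (Fisher's exact test, p = 0.000318, adjusted 0.00159). The test treats genes as independent, which genes that vary together across libraries are not. The genes higher by diet and lower by RNAi included CG13643, Osi7 and, outside the naming rule and chosen after their values were seen, CG16886 and CG34461. CG13643 had log2 changes of 1.25 on the sugar diet and -1.13 with OGT RNAi, Osi7 of 1.01 and -1.28, CG16886 of 1.03 and -1.11 and CG34461 of 1.18 and -1.02. The metallothionein gene MtnA was lower on the sugar diet (-1.26) and higher with RNAi (0.77), as were CAH2 (-0.39 and 0.52) and DNaseII (-0.56 and 0.62), 3 genes against 2.78 expected (exact p = 0.758). Higher in both were CG5773 (0.86 and 0.77), Cpr65Au (0.52 and 0.48), the chitin deacetylase gene serp (0.56 and 0.45), CG9519 (0.48 and 0.51) and CG7299 (0.38 and 0.80), 5 against 2.46 expected (exact p = 0.099). Lower in both were 0 genes against 0.712 expected (exact p = 1). Without control diet replicate 1 (195 genes called) Osi7 and Cpr65Au lost their diet call, and without Gal4 control replicate 1 (43) CG13643, Osi7 and Cpr65Au lost their RNAi call. CAH2, DNaseII, serp, CG9519 and CG7299 also lie outside the naming rule and were chosen after their values were seen.

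**Figure D3:**
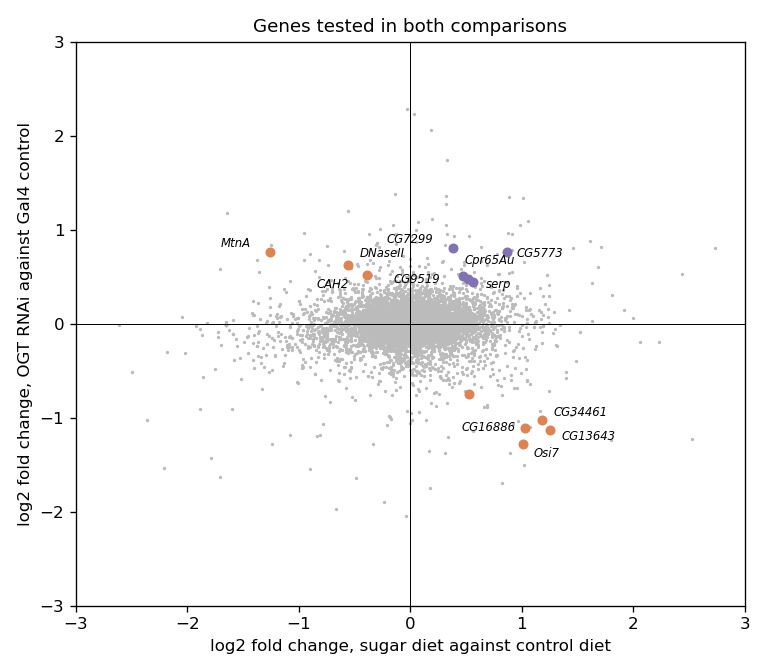
Log2 change with OGT RNAi (y axis) against log2 change on the sugar diet (x axis) for genes tested in both comparisons, with 1 grey point per gene (8603 drawn, 11 outside the axes) and the 13 genes called in both in colour. Orange marks the 8 genes that went in opposite directions and violet the 5 higher in both.

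As sets in the RNAi comparison, the 258 genes called higher by diet and the 292 called lower were both shifted down relative to other genes. Their medians were -0.07 (camera p = 0.00275) and -0.08 (camera p = 8.75e-06), and with an estimated correlation the p-values were 0.276 and 0.247. Across the 8614 genes, which are not independent replicates, the log2 changes of both comparisons had a Pearson correlation of 0.032 and a Spearman correlation of 0.021. The shared genes numbered 4 and 7 without control diet replicate 1 (exact p = 0.289) or 2, 8 and 7 without Gal4 control replicate 1 or 4, and 47 without OGT RNAi replicate 4. The diet-higher and RNAi-lower genes numbered 1 and 2 without Gal4 control replicate 1 (exact p = 0.192) or 2 (exact p = 0.0571), and 3 and 2 without replicate 3 or 4. They numbered 3, 8, 15 and 3 without OGT RNAi replicate 1, 2, 4 or 5, and 2 without control diet replicate 1. The diet-higher set lost its shift without sugar diet replicate 1 or Gal4 control replicate 4 (medians of -0.04), and without Gal4 control replicates 3 and 4 there was 1 shared gene.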

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

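Chosen only after the result was seen were the tests of the fat body share, of a common fall of all genes and of eye RNA as the source of the photoreceptor transcripts. The same holds for the alternatives without Gal4 control replicates 3 and 4, without OGT RNAi replicates 1 and 2, without the length trend, without Arc1 and CG15579, and with 1 gene of each identical set.

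Of 196 groups of 4 or 5 values of named genes, 9 held a library far from the others, and chance gives 9.8 at a rate of about 1 in 20. Among the OGT RNAi libraries, replicate 4 stood out for Adgf-A (414.9 CPM, the others 307.5 to 337.5) and fru (141.2 CPM, the others 124.6 to 127.5). Replicate 1 stood out for ninaE (1.597 CPM, the others 0.551 to 0.7388) and tim (134.9 CPM, the others 92.59 to 104.2). Replicate 3 stood out for Orco (7.714 CPM, the others 2.832 to 4.213) and replicate 2 for sxc (170 CPM, the others 133.5 to 137.8). Among the Gal4 control libraries, replicate 2 stood out for Gr64e (21.6 CPM, the others 17.72 to 18.17), and replicate 4 for ninaE (576.3 CPM, the others 1.125 to 27.71) and trpl (53.77 CPM, the others 0.6 to 4.496).

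The photoreceptor genes in Gal4 control replicate 4 formed a pattern. If RNA of eye tissue were the source, most photoreceptor markers would be highest in that library, and 16 of the 18 measured markers were, led by ninaE, Arr2 (161.6 CPM) and Arr1 (106.4 CPM), with 13 second highest in replicate 3. RNA from the eye, which lies in the same head and which no sort would have removed, is therefore a candidate source, although norpA and rdgB are expressed in all 9 libraries and 5 of the markers also stand on the G protein list. Without these 2 libraries all 119 called genes kept an unadjusted p under 0.05 in the same direction. Their differences therefore do not rest on these 2 libraries alone. The 119 had been chosen with the other libraries included, which favours this outcome. Only 4 stayed called, against 71 without OGT RNAi replicates 1 and 2. The retest does not decide how far eye RNA added to the calls. The eye RNA could have come with the dissection, and no biological explanation was tested for it.

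Lower lipogenesis genes on the sugar diet could reflect a smaller share of fat body RNA, a few genes taking more of the reads, a transcript length trend, or regulation by the diet. A smaller share of fat body would lower its markers alike. Of 6 markers, 3 (to, Npl4 and apolpp) stayed above the lipogenesis median of -0.83 by more than 2 standard errors. However, to and Npl4 are not confined to that tissue, which leaves apolpp (-0.40). Lsp1beta, Est-6 and Mtp had log2 changes of -1.35, -1.09 and -0.82, so the markers do not decide this. Log2 changes did not follow transcript length in this comparison (Spearman -0.002). With the length trend removed 10 of the 10 falling lipogenesis genes stayed called and lower. That removal moved their log2 changes by a median of only 0.0114, so it adds little. Reads taken by a few genes would lower all other genes alike. On the TPM scale, without TMM, the median of all genes was -0.267 and that of the 10 genes was -1.082 (SD 0.315). The 10 had been picked as called lower, which favours such a gap. The whole lipogenesis list, called or not, had a median of -0.61 there. The values on length and on the TPM scale argue against a length trend and a common fall of all genes as the whole cause. A smaller share of fat body RNA stays open. Removal of the counts of Arc1 and CG15579 kept 10 as well but moved the log2 changes of these genes by a median of 0.0011, so it decides nothing. Regulation by the diet stays open as a hypothesis, since it was found in these same samples.

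The list results under OGT RNAi are less firm. A length trend may have raised the ribosomal list and lowered the receptor list, but with the trend removed the ribosomal list kept a camera p of 1.117e-05. Its median was then 0.05 against 0.118, so the trend could account for most of the size. That p rests on the preset correlation. With its estimated correlation of 0.844 the list had a camera p of 0.305 even before the trend was removed. The test therefore cannot decide whether the trend is the whole cause. The sweet receptor list then had a camera p of 0.007147 and a median of -0.35 against -0.34, and with an adjusted p of 0.0762 it was no longer called. Eye RNA in the control libraries would not lower the sweet list, whose median was -0.428 without them. However, 62 of 100 splits of the 9 samples gave at least as many called lists as the real 5, with up to 18, so chance cannot be excluded for the list count. An effect of OGT RNAi on these lists remains open.

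Other splits of the 9 OGT RNAi and Gal4 control samples into 5 and 4 were counted, 100 of 126. As many called genes as the real 119 came from 3 splits, the real one included, so a count of this size was rare among the splits. Splits that mixed the groups also reached it. The count alone therefore does not tell an effect of OGT RNAi from another structure of the samples. As many shared genes as the real 13 came from 4, but the shared genes rise with the number of calls: another split with 107 called genes shared 15, and one with 164 shared 16. The splits therefore do not exclude chance for the overlap. Genes higher by diet and lower by RNAi were not counted separately in the splits. The highest other split called 752 genes and shared 51, which points to a structure of the samples: it set OGT RNAi replicates 1 and 2 with Gal4 control replicates 1, 3 and 4 apart from the rest. Within the OGT RNAi group, replicates 1 and 2 had more para (136.8 and 160.6 CPM, the others 37.77 to 50.11) and fne (36.8 and 49.07 CPM, the others 11.96 to 14.9), which is why these 2 libraries were left out in an alternative. For the shift of diet-responsive genes, 29 of 100 splits gave a camera p as small as the real 8.749e-06, the smallest being 6.89e-16, so chance cannot be excluded.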

How the results depend on the processing

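The removed length trend, the counts without Arc1 and CG15579, the omission of Gal4 control replicates 3 and 4 or of OGT RNAi replicates 1 and 2, and the use of 1 gene of each identical set were chosen after seeing the data. In the diet comparison the calls numbered 312 with a minimum of 1.5-fold, 300 in a single fit of 4 groups and 306 with DESeq2, and the other complete-sample settings stayed within 1.5 times of 571. For called genes named in the text, 937 of 1140 alternative values kept direction and call, 202 kept the direction only and 1 changed sign; with OGT RNAi it was 462 of 627, with 165 and 0. No list was called with an estimated correlation (0 in either comparison), and with fry 0 diet lists and 1 OGT RNAi list were.

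In the OGT RNAi comparison the calls numbered 65 with a minimum of 1.5-fold, 254 with DESeq2, 4 without Gal4 control replicates 3 and 4 and 71 without OGT RNAi replicates 1 and 2. The called lists numbered 3 with RLE factors, 8 without a filter, 2 with the length trend removed, 9 without OGT RNAi replicates 1 and 2, and 3 with 1 gene of each identical set. The shared genes numbered 7 with limma on TPM (exact p = 0.108) and 1 without Gal4 control replicates 3 and 4 (exact p = 0.234). Those higher by diet and lower by RNAi numbered 1 (exact p = 0.115) and 0 (exact p = 1) under these settings. More genes were shared with DESeq2 (26, exact p = 1.3e-09), without a filter (23, exact p = 6.77e-05) and with the length trend removed (23, exact p = 0.000225). At an unadjusted p under 0.05 in both comparisons 274 were shared (exact p = 3.85e-11). The exact test treats genes as independent, which they are not. The diet-higher set lost its shift without Gal4 control replicates 3 and 4 (median -0.027), and the diet-lower set without OGT RNAi replicates 1 and 2 (median -0.045). With an estimated correlation and with fry the medians, by construction the same at -0.066 and -0.084, were not past the threshold. The cause was not tested.

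A block for the replicate number gave 728 called diet genes, 8 diet lists, 63 OGT RNAi genes, 3 OGT RNAi lists, and 1 gene higher by diet and lower by RNAi (exact p = 0.448). Not called under it were the P450 and fat body lists of the diet comparison (adjusted p = 0.0599 and 0.0822) and the sweet receptor, oxidative phosphorylation and insulin lists of the RNAi comparison (0.0687, 0.235 and 0.102). The replicate numbers do not pair the samples: after removal of the group means, libraries of like number were correlated across genes at 0.005 and 0.005 in the diet comparison and at 0.164, -0.249, -0.021 and -0.047 in the RNAi comparison.

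Leaving out 1 library at a time gave 195 to 938 diet genes, 9 to 13 diet lists, 42 to 265 OGT RNAi genes, and 2 to 10 OGT RNAi lists. It gave 4 to 47 shared genes, 1 to 15 genes higher by diet and lower by RNAi, and medians of -0.123 to -0.038 and -0.137 to -0.05 for the diet-higher and diet-lower sets. In the diet comparison a single library left on one side was assumed to vary like the other group. Of the genes not called, those that changed sign ranged from -0.8 to 0.205 (Gr5a), -0.159 to 0.02 (Gr64d), -0.233 to 0.063 (norpA in the diet comparison) and -0.282 to 0.735 (Or71a in the diet comparison). They ranged from -0.017 to 0.244 (Gr64a), -0.145 to 0.118 (v), -0.067 to 0.012 (msl-2) and -0.413 to 0.418 (Orco) with OGT RNAi. Other changes of sign were Gr64d with a length offset (0.056), Sh, mmy and elav with limma on TPM (-0.041, -0.036 and -0.156). With OGT RNAi they were msl-2 and the oxidative phosphorylation list with the length trend removed (0.003 and -0.005), Gr64a and v without Gal4 control replicates 3 and 4 (-0.09 and 0.328), and Scr and v without OGT RNAi replicates 1 and 2 (-0.016 and 0.16). Most receptor genes lay under 10 CPM in the diet libraries, and whether depth limited their calls was not tested. All alternatives fixed beforehand were run, but set tests had no counterpart in DESeq2, limma on TPM and the single fit.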

Other observations

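The genes of both hypotheses below had not been looked at when their tests were set. CG11089 and Nmdmc, enzymes of purine synthesis and folate metabolism, and CG3999, of glycine breakdown, were among the strongest falls on the sugar diet, and a hypothesis was that other genes of one-carbon and purine metabolism fell too. Of 12 such genes not looked at before, 5 were called lower and none higher, with a median log2 change of -0.52 and a camera p of 0.0009906, and a p of 0.0739 with an estimated correlation. They were ade2 (-0.81), AdSL (-0.93), Prat2 (-0.89), CG8665 (-0.75) and Gnmt (-1.08), while AdSS had 0.35 and was not called. Of the 7 that passed adjusted over the list alone, AdSS was higher. The median was negative, as a fall of the pathway as a group would give, but the estimated correlation leaves it open. The hypothesis came from the same libraries in which it was tested. Whether a smaller share of fat body RNA lowered these genes was not tested.

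A second hypothesis was that the pentose phosphate pathway, which supplies NADPH for fatty acid synthesis, fell with the lipogenesis genes. Of 5 such genes 2 were called lower, Pgd (-0.46) and Zw (-0.42, the glucose-6-phosphate dehydrogenase gene), and 3 passed adjusted over the list alone, with a median of -0.42, a camera p of 0.001695 and a p of 0.116 with an estimated correlation. A joint fall would give such values, and the estimated correlation likewise leaves it open. The same libraries gave the hypothesis and the test here too, and the share of fat body RNA was not tested for these genes.

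Some genes outside the naming rule were chosen after their values were seen. CG11313 had 2.72 ± 1.16 CPM with OGT RNAi (n = 5) and 0.0229 ± 0.0459 CPM in the Gal4 control (n = 4). CG15696 had 1.67 ± 0.695 and 0.0459 ± 0.0918 CPM, and Spn28F, a serpin gene, had 3.80 ± 1.75 and 0.367 ± 0.17 CPM. Whether these differences came from RNA interference or from a difference between the fly strains cannot be told apart, as the Gal4 control lacked the UAS transgene. CG15579 varied widely within the diet groups, with 84150 and 22860 CPM on the sugar diet and 15700 and 348 CPM on the control diet.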
